A study of Mus musculus with 28 samples.

How the data were processed

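The series measured total RNA of mouse cells by sequencing, with libraries made with the NEBNext Ultra kit per the labels' protocols. The submitters' processing notes name Bowtie2, HISAT2, RSEM, R 3.4.2 and DESeq2 and the genome build mm10, and their roles, order and other versions are not given in the sources used here. The authors deposited 1 table of 53564 gene symbols with TPM (transcripts per 1000000 in all) for each library, and each column used adds up to 1000000. Read counts were not used here, so the depth of each library is unknown, no interval or detection limit that needs a count is given, and a value of 0 is reported as listed at 0.

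Samples were grouped by the names of the columns, which match the sample titles for 16 libraries in 8 groups of 2. The series holds 28 samples in 14 groups. The remaining 12 columns carry 6 names that each occur 2 times, those of the epiblast-like cells, and 6 titles, those of the day-4 PGC-like cells, have no column. These 12 columns cannot be matched to 1 sample each by name and were not used in any step. The plan of 28 libraries and 21 comparisons, fixed before the data were examined, therefore became a fit of 16 libraries with 8 of the planned comparisons. A further 4 were added after the data were seen, namely ST and RT 1dMeioLC each against PGC-1dMeioLC, and the differences between the stages (1dMeioLC against 1dEB) in the ST minus LT and the RT minus ST effect.

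Genes with at least 1 TPM in at least 2 libraries were kept, 21935 in all. Values were taken as log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3 (a group mean per group, empirical Bayes moderation with a trend on mean expression, 8 residual and 2.23 prior degrees of freedom, no replicate block), with a 2-sided moderated test per gene. Benjamini-Hochberg adjustment was over the genes kept within each comparison, with a threshold of 0.05 on the adjusted p. Standard errors are limma's. The spread is shared by all 8 groups, and replicate numbers were not taken as pairs.

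A set of 27 gene lists was written before the data were examined: early PGC, late germ cell, meiosis, retinoic acid response, naive pluripotency, formative and primed pluripotency, primitive streak and mesoderm, endoderm, ectoderm and neural, MAPK feedback and immediate early, TGFb and Nodal pathway, BMP pathway, p53 targets, proliferation, telomere maintenance, two-cell-like, DNA methylation and reprogramming, interferon and innate response, imprinted, hypoxia and glycolysis, cholesterol biosynthesis, gonadal somatic cell markers, fibroblast and stroma markers, blood and endothelial markers, sex-linked, mitochondrially encoded and replication-dependent histone genes. Of their names 10 were found in the table under another symbol and 2 (Dux and Eif1ad8) were not found. Lists were tested with limma's camera at its preset correlation of 0.01, 2-sided, adjusted over the lists within a comparison, and again with a correlation estimated for each list. A list's count of called genes is given over all genes tested and, where stated, adjusted over the list alone. Lists overlap in members, so their calls are not independent.

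Genes were named by a rule fixed before the data were examined. It names 15 anchors (Terc, Tert, Prdm1, Prdm14, Tfap2c, Nanos3, Dppa3, Kit, Ddx4, Dazl, Stra8, Sycp3, T, Cdkn1a and Mki67) wherever measured. It adds up to 4 members of each list with the largest change among those past the threshold. It also takes the 5 highest and 5 lowest changes of ST against LT, and the 3 highest and 3 lowest of other comparisons, among genes with at least 10 TPM in the higher group and no overlap between the groups' libraries. Symbols that start with Gm and a digit or end in Rik were left out, differences between stages used the mean of the highest group and no overlap rule, and a gene named in 1 comparison may be given in others. Some genes that the rule names are not reported here. Wt1, Wnt4, Uty, Zfy1 and Ddx3y in ST against LT 1dMeioLC, and the per-library values of genes listed at 0, were chosen after their values were seen. Coordinates are those of GENCODE M21 on mm10, joined by symbol (53310 of the 53564 symbols had 1 record), and 24 symbols had been turned into dates in the table.

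Overlaps of calls were compared with the product of both counts divided by the genes tested and with 100 simulations of libraries with no effect that kept the shared groups. Covariances and correlations of fold changes are across genes, which are not independent replicates. Strand use in counting is not given in the sources used here, so reads of Xist and its antisense Tsix were not separated here.

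The gene test was checked on simulated data, with known changes set in genes of at least 5 TPM among the 21935 and noise drawn from the fitted spread. For ST against LT 1dEB it recovered 88% of 100 genes changed by 1 on the log2 scale and 93% of 100 changed by 2, with 14 false among 195 calls. For ST against LT 1dMeioLC the shares were 86% and 94%, with 3 false among 183 calls. The list test called 1 of 27 lists when the p53 targets alone were raised by 0.5 in ST against LT 1dEB, and it was that list. Noise was drawn for each gene on its own, so this check does not test the preset correlation of the list test.

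Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a mean of at least 5 TPM (9611 genes), median-of-ratios scaling, quantile normalization, a fit of the compared stages alone, array weights, a replicate block over all groups or within each stage, leaving out each library in turn, and the estimated list correlation. Protein-coding scaling, in which the TPM of nuclear protein-coding genes (21777 in the table) are set to the same total in each library, was chosen after the data were seen, because rRNA genes took unequal shares of TPM. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.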

Results

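RNA was sequenced from mouse cells (strain C57BL6) on the way from embryonic stem cells to primordial germ cells (PGCs, the embryonic precursors of eggs and sperm) and on into early meiosis. The stem cells were of 3 kinds: LT was wild type with long telomeres, ST lacked Terc, the RNA template of telomerase, came from generation 4 of the knockout and had short telomeres, and RT had Terc and telomere length rescued. Cells grown for 2 days as epiblast-like cells were aggregated for 1 day with BMP4, SCF, EGF and LIF, which gave day-1 embryoid bodies (1dEB). After 4 days of that induction, PGC-like cells were cultured for 1 day with GFP-marked somatic cells of female E12.5 gonads and 3 µM retinoic acid, and GFP-negative cells were sorted as 1dMeioLC (meiocyte-like cells). PGCs of E10.5 embryos were sequenced directly (E10.5PGC) or after the same culture (PGC-1dMeioLC). The 16 libraries compared here formed 8 groups of 2, namely LT, ST and RT at 1dEB and at 1dMeioLC and both PGC groups. Samples of epiblast-like cells and of day-4 PGC-like cells were not analysed here.

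Values were transcripts per 1000000 (TPM), which added up to that total in each library, so the read depth behind a value is unknown. Between 13900.5 and 16643.5 genes per group reached 1 TPM on average, and 21935 genes were tested. The libraries differed in make-up. Genes of the chromosome 17 rRNA-like locus took 27.4% ± 0.12 (SD, n = 2) of TPM in LT 1dEB, 24.0% ± 0.62 in ST 1dEB and 39.0% ± 1.8 in RT 1dEB, against 1.90% ± 0.013 in LT 1dMeioLC and 9.17% ± 0.061 in ST 1dMeioLC. Both mitochondrial rRNAs, mt-Rnr1 and mt-Rnr2, added 12.8% ± 0.55 in RT 1dEB and 3.86% ± 0.11 in ST 1dEB. Nuclear protein-coding genes were left with 28.1% ± 1.4 of TPM in RT 1dEB and 44.2% ± 0.23 in ST 1dEB. Comparisons with RT 1dEB are therefore given with the nuclear protein-coding total set equal in every library, except where raw TPM is named. This scaling, called protein-coding scaling here, was chosen after the data were seen. It raises all values but keeps the pseudocount of 1, so it also changes the weight of low values. Counts of calls in the closing sections are of raw TPM unless a scaling is named.

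**Figure D1:**
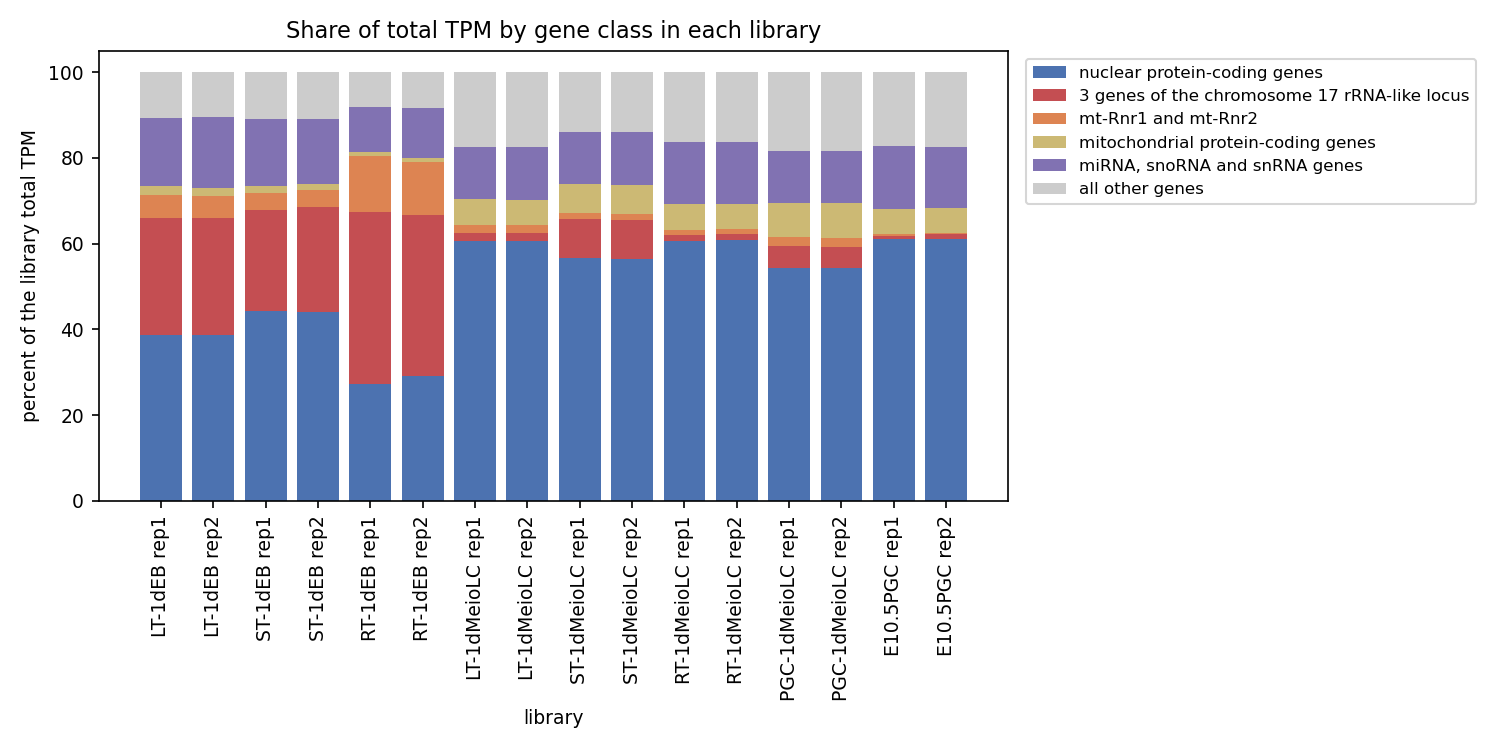
Percent of each library's total TPM (vertical axis, stacked bars) by gene class for the 16 libraries (horizontal axis). Nuclear protein-coding genes took 28.1% in RT 1dEB and 38.7% in LT 1dEB, against 60.6% in LT 1dMeioLC.

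Terc, the deleted and restored gene (mm10 chromosome 3, 96414437 to 96414859, GENCODE M21), was listed at 0 in all 4 ST libraries. LT libraries held Terc at 0.921 and 1.70 TPM at 1dEB and at 2.35 and 5.39 TPM at 1dMeioLC, and RT libraries at 3.35 and 1.75 TPM and at 3.08 and 0.699 TPM. These values match the labels of the knockout and rescued lines. Terc stood at 0.945 and 0.974 TPM in E10.5PGC and was listed at 0 in both PGC-1dMeioLC libraries, for which the labels give no knockout. At such low levels some of the Terc calls were fragile. In ST against LT 1dEB the limma Benjamini-Hochberg adjusted p went from 0.039 to between 0.059 and 0.2 when any 1 of the 4 libraries was left out. In RT against ST 1dMeioLC it went from 0.023 to 0.17 without RT replicate 1, 0.082 without ST replicate 1 and 0.079 without ST replicate 2. Tert, the telomerase protein, was measured at 3.24 TPM in LT 1dEB and 2.35 TPM in ST 1dEB, where it was not called.

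Libraries of 1 group correlated across genes with Pearson's r of 0.970 to 0.985. The first principal component held 51.5% of the variance and set the 1dEB libraries apart from all others, the second held 16.9% with E10.5PGC at one end and both ST groups at the other, and the third held 6.2%. All p-values of genes come from limma on log2(TPM + 1) with Benjamini-Hochberg adjustment and measure the spread between these libraries, not between independently derived lines. Because limma pools the spread over all 8 groups, small differences pass, so sizes are given beside calls. The gene lists were fixed before the data were examined, and adjusted over the list alone the count of a list differed from that over all genes by at most 4 members in each direction in any comparison.

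Telomere shortening was first compared in ST and LT at 1dEB, the question of the series for PGC, somatic and proliferation genes. Cdkn1a, the p53-driven inhibitor of the cell cycle (chromosome 17, 29090976 to 29100727), was at 77.6 ± 0.402 TPM (SD, n = 2) in LT and 841 ± 11.1 TPM in ST, a log2 fold change of 3.42 (SE 0.06, limma adjusted p = 2.3e-10). Mdm2, which encodes the ubiquitin ligase of p53, rose by 2.04 and Phlda3, an inhibitor of Akt signalling, by 2.72 to 310 ± 8.40 TPM. Of 25 p53 targets, 22 were higher, 0 lower and 3 not called, and adjusted over the list alone 22 were higher (camera adjusted p = 1.7e-08). Proliferation genes went the other way. 23 of 26 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 7.5e-16), among them Cdc6 (-1.27), a loader of replication origins, Top2a (-1.15), the DNA topoisomerase of dividing cells, Birc5 (-1.08), survivin, and Aurkb (-0.96), a mitotic kinase. Mki67, the proliferation marker, fell from 12.4 ± 0.493 to 7.55 ± 0.442 TPM (log2 fold change -0.65, SE 0.11, adjusted p = 9.2e-04).

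PGC genes did not move together in ST 1dEB. Dppa3, a maternal factor switched on in PGCs (chromosome 6, 122626410 to 122630272), fell from 48.0 ± 4.35 to 20.8 ± 0.563 TPM (SD, n = 2, log2 fold change -1.17, SE 0.07, limma adjusted p = 4.2e-07). Nanos3, an RNA-binding survival factor of PGCs, rose from 4.81 ± 1.73 to 13.6 ± 2.52 TPM (adjusted p = 9.5e-05), and Prdm1, the repressor that starts the PGC programme, rose by 0.76 (adjusted p = 3.2e-04). The X-linked homeobox genes Rhox6, Rhox9 and Rhox5, of a family whose copies may share reads, were lower, with log2 fold changes of -3.35, -2.04 and -1.60. T, the mesoderm factor brachyury, was at -0.75 (adjusted p = 0.0021) and Stra8, the gatekeeper of meiosis, at -0.88 (adjusted p = 0.0022). Among the 15 genes set as anchors before the data were examined, 4 were higher (Cdkn1a, Prdm1, Prdm14 and Nanos3), 8 lower (Kit, Sycp3, Tfap2c, Stra8, Mki67, Dppa3, T and Terc) and 3 not called (Tert, Ddx4 and Dazl). Several of these calls were lost when 1 library was left out. The call of Prdm14 was lost without LT replicate 1 (0.059) or ST replicate 1 (0.062), and the calls of Tfap2c (0.12 and 0.10), Kit (0.18 and 0.12) and Sycp3 (0.11 and 0.13) without LT replicate 1 or ST replicate 2. Dazl was called without LT replicate 2 (0.0099) and Ddx4 without ST replicate 2 (0.039), both lower in ST, and protein-coding scaling called Dazl (0.0088) and Tert (0.043) lower. Of 20 early PGC genes, 6 were higher, 11 lower and 3 not called, the same adjusted over the list alone (camera adjusted p = 0.0027; adjusted p = 0.08 with an estimated correlation).

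Stroma markers were higher in ST 1dEB. Col1a1, a collagen chain of connective tissue (chromosome 11, 94936224 to 94953042), rose from 2.93 ± 0.0354 to 94.3 ± 0.488 TPM (SD, n = 2, log2 fold change 4.60, SE 0.09, limma adjusted p = 3.8e-10). Mgp, a calcification inhibitor of matrix, rose by 4.60, Dcn, the proteoglycan decorin, by 4.06 and Col6a1, a chain of collagen VI, by 4.04. 15 of 16 fibroblast and stroma markers were higher, with or without adjustment over the list alone (camera adjusted p = 3.4e-14). Interferon and innate response genes followed, with 19 of 21 higher and 1 lower, 20 and 1 adjusted over the list alone (camera adjusted p = 3.1e-10). Their largest changes were in Ifit3 (3.96), Usp18 (3.83), Ifit1 (3.26) and Irf7 (3.15), antiviral effectors and regulators. Endoderm genes were called with 10 of 20 higher (camera adjusted p = 0.0014; adjusted p = 0.059 with an estimated correlation), primitive streak and mesoderm genes with 13 of 25 higher (adjusted p = 0.034; 0.08) and BMP pathway genes with 11 of 18 (adjusted p = 0.0027; 0.074), where Bmp2, a BMP ligand, rose by 3.55 and Snai1, a driver of epithelial to mesenchymal transition, by 3.04. S100a4, a calcium-binding protein of fibroblasts, and Npy, neuropeptide Y, were among the 5 highest genes that the naming rule allows, at 4.83 and 4.68. Whether stromal feeder cells were used under the stem cells is not given in the sources used here.

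Imprinted genes, expressed from 1 parental copy, went both ways in ST 1dEB. H19, a maternally expressed RNA, rose from 8.07 ± 0.887 to 196 ± 0.624 TPM (SD, n = 2, log2 fold change 4.45, SE 0.06, limma adjusted p = 4.9e-11), and Igf2, its neighbouring growth factor, by 4.10. Mest, a paternally expressed hydrolase (chromosome 6, 30723547 to 30748465), fell from 28.2 ± 0.621 to 0.963 ± 0.0413 TPM (log2 fold change -3.89, SE 0.06, adjusted p = 4.9e-11). The imprinted list was not called, with 9 higher and 6 lower of 21 (camera adjusted p = 0.45). Cholesterol biosynthesis genes were lower in 8 of 20 (adjusted p = 2.0e-04), with Insig1, a sterol sensor, at -0.82. Telomere maintenance genes were lower in 9 of 22 and higher in 3 (adjusted p = 0.0013), meiosis genes lower in 15 of 35 (adjusted p = 7.9e-05) and mitochondrially encoded genes lower in 12 of 15 (adjusted p = 1.2e-07). Late germ cell genes were lower in 4 of 19 (adjusted p = 0.0034; 0.063 with an estimated correlation), primed pluripotency genes in 9 of 18 (adjusted p = 0.017; 0.059). MAPK feedback genes were higher in 11 of 20 (adjusted p = 0.0047; 0.15), TGFb and Nodal pathway genes in 13 of 20 (adjusted p = 0.02; 0.059) and two-cell-like genes in 8 of 12 (adjusted p = 0.034; 0.078). No call was made for the retinoic acid response (adjusted p = 0.076), naive pluripotency (0.78, with a median of 0.03 but a test direction of down), ectoderm (0.78), DNA methylation (0.051), hypoxia (0.85), gonadal somatic (0.076), blood and endothelial (0.51), sex-linked (0.18) or histone genes (0.45).

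In that comparison 8417 genes were called, 5866 higher and 2551 lower in ST, and 2543 and 482 of them changed by at least 2-fold. The split depended on scaling. With protein-coding scaling the median of all genes moved from 0.10 to 0.00 and the split became 4817 and 4110, and with quantile normalization the median was -0.06 and the split 4061 and 5162. With protein-coding scaling 19 of 25 p53 targets and 19 of 21 interferon genes were still higher and 25 of 26 proliferation genes lower. With a correlation estimated for each list in place of the preset one, 8 of the 17 list calls held, those of p53 targets, proliferation, interferon, stroma, mitochondrial, cholesterol, telomere maintenance and meiosis genes.

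Rescued cells were compared at 1dEB with ST, to see what moved back, and with LT, to see what still differed. Cdkn1a was at 283 ± 15.7 TPM (SD, n = 2) in RT, between both other lines, and with protein-coding scaling it was lower than in ST by a log2 change of -0.92 (limma adjusted p = 1.7e-06) and higher than in LT by 2.32 (adjusted p = 8.2e-09). As a list the p53 targets were not called against ST. With that scaling 3 of 25 were higher and 7 lower in RT than in ST (camera adjusted p = 0.36). Raw TPM gave 1 and 19 (camera adjusted p = 0.03, and 0.25 with an estimated correlation). Against LT, 21 of 25 were higher in RT with protein-coding scaling (camera adjusted p = 9.0e-07). Raw TPM gave 13 higher and 3 lower there (camera adjusted p = 1.2e-05). Interferon genes were lower than in ST in 14 of 21, with Ifit3 at -1.92 (camera adjusted p = 1.3e-06), and stroma markers in 13 of 16, with Dcn at -2.06 and Col6a1 at -2.52 (adjusted p = 1.6e-07). Both lists were still above LT, in 15 of 21 and 16 of 16. H19 was lower than in ST (-2.26) and Igf2 as well (-1.25).

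The counts of proliferation genes depended on the scaling in RT against ST 1dEB. Raw TPM put 13 of 26 lower and 2 higher in RT and did not call the list (median -0.20 but a test direction of up, camera adjusted p = 0.91), around a median of all genes of -0.38. Protein-coding scaling put 1 lower and 21 higher (camera adjusted p = 8.7e-08). Against LT, RT had lower proliferation genes with both, 24 of 26 with raw TPM and 13 with protein-coding scaling (adjusted p = 1.1e-06), with Birc5 at -1.01 and Ccne1, cyclin E, at -1.38. Mki67 was called lower in RT than in LT with raw TPM (-0.59) and not called with protein-coding scaling (-0.18, adjusted p = 0.23). Early PGC genes were lower in 8 of 20 and higher in 2 with raw TPM in RT against ST, not called as a list (median -0.16 but a test direction of up, camera adjusted p = 0.79), and higher in 11 and lower in 3 with protein-coding scaling (camera adjusted p = 0.014; adjusted p = 0.059 with an estimated correlation). Dppa3 stayed below LT at 21 ± 1.40 TPM (SD, n = 2, protein-coding scaled log2 fold change -0.73, limma adjusted p = 1.8e-05) and Nanos3 above it (1.98), T was lower than in LT (-2.23), and Mest was at 0.628 ± 0.0938 TPM, far below LT (-4.51). Rhox6, Rhox9 and Rhox5 were also below LT (-2.43, -1.95 and -1.66). With that same scaling ST against LT stood at -3.91, -2.60 and -1.79 for these genes. It stood at -1.38 for Dppa3, 1.28 for Nanos3, -0.99 for T and -4.54 for Mest. Of the 15 anchors, raw TPM called 3 higher (Tfap2c, Stra8 and Terc) and 4 lower (Cdkn1a, Prdm1, Prdm14 and T) in RT than in ST, and 2 higher (Cdkn1a and Nanos3) and 4 lower (Ddx4, Mki67, Dppa3 and T) in RT than in LT. Protein-coding scaling called 10 higher (Kit, Dazl, Sycp3, Tert, Tfap2c, Stra8, Mki67, Dppa3, Nanos3 and Terc) and 3 lower (Cdkn1a, Prdm1 and T) in RT than in ST, with no call of Prdm14 (0.19), and 4 higher (Cdkn1a, Tfap2c, Stra8 and Nanos3) and 2 lower (Dppa3 and T) in RT than in LT, with no call of Ddx4 (0.46). The raw call of Ddx4 was also lost without LT replicate 1 (0.25) or RT replicate 2 (0.24).

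Raw TPM called 10905 genes in RT against ST 1dEB, 1127 higher and 9778 lower, around a median of all genes of -0.38. With protein-coding scaling the median was 0.05 and the calls were 7822, 4084 higher and 3738 lower. In RT against LT the 9132 raw calls were 2346 higher and 6786 lower (median -0.17), and the 8318 scaled calls 5156 higher and 3162 lower (median 0.10). Endoderm genes were lower in RT than in ST in 10 of 20 (camera adjusted p = 5.8e-05), two-cell-like genes in 8 of 12 (0.0019). Meiosis genes were higher in 18 of 35 (camera adjusted p = 9.6e-05). With raw TPM 3 meiosis genes were higher and 2 lower (camera adjusted p = 5.7e-05, and 0.058 with an estimated correlation). Cholesterol biosynthesis genes were lower than in LT in 12 of 20 (3.7e-05). S100g, a calcium-binding protein, and S100a8, a calgranulin, were among the lowest genes that the naming rule allows in RT against ST (-5.72 and -4.65). With raw TPM no list call of RT against ST held with an estimated correlation, and 5 of RT against LT did, those of p53 targets, proliferation, interferon, cholesterol and stroma genes.

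ST and LT were then compared at 1dMeioLC, which asked how germ cell and meiosis genes fared. Dppa3 was at 509 ± 20.4 TPM (SD, n = 2) in LT and 28.6 ± 1.42 TPM in ST, a log2 fold change of -4.11 (SE 0.07, limma adjusted p = 6.6e-10). Ddx4, an RNA helicase of germ cells (chromosome 13, 112598333 to 112652475), fell from 35.1 ± 3.22 to 5.91 ± 0.0987 TPM (-2.38, SE 0.19, adjusted p = 1.3e-05), and Dazl, the RNA-binding licensing factor of gametogenesis (chromosome 17, 50279395 to 50293636), from 344 ± 7.36 to 84.3 ± 5.25 TPM (-2.02, SE 0.09, adjusted p = 4.0e-07). Stra8 (chromosome 6, 34920163 to 34939344) went from 852 ± 8.76 to 330 ± 9.35 TPM (-1.37, SE 0.17, adjusted p = 2.4e-04) and Sycp3, a protein of the chromosome axis in meiosis, from 198 ± 3.90 to 76.6 ± 4.00 TPM (-1.36, SE 0.20, adjusted p = 5.0e-04). Of 19 late germ cell genes, 18 were lower, 0 higher and 1 not called, and 18 were lower adjusted over the list alone (camera adjusted p = 1.6e-13). Mov10l1 (-2.74) and Mael (-2.32), of the piRNA pathway, and Slc25a31 (-2.61), an ATP carrier of germ cells, fell most beside Ddx4. Of 35 meiosis genes, 20 were lower, 1 higher and 14 not called, and 22 were lower adjusted over the list alone (adjusted p = 9.0e-08), with the cohesin Stag3 at -1.99, Hormad2, an axis protein, at -1.84 and Tex12, of the synaptonemal complex, at -1.82.

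**Figure D2:**
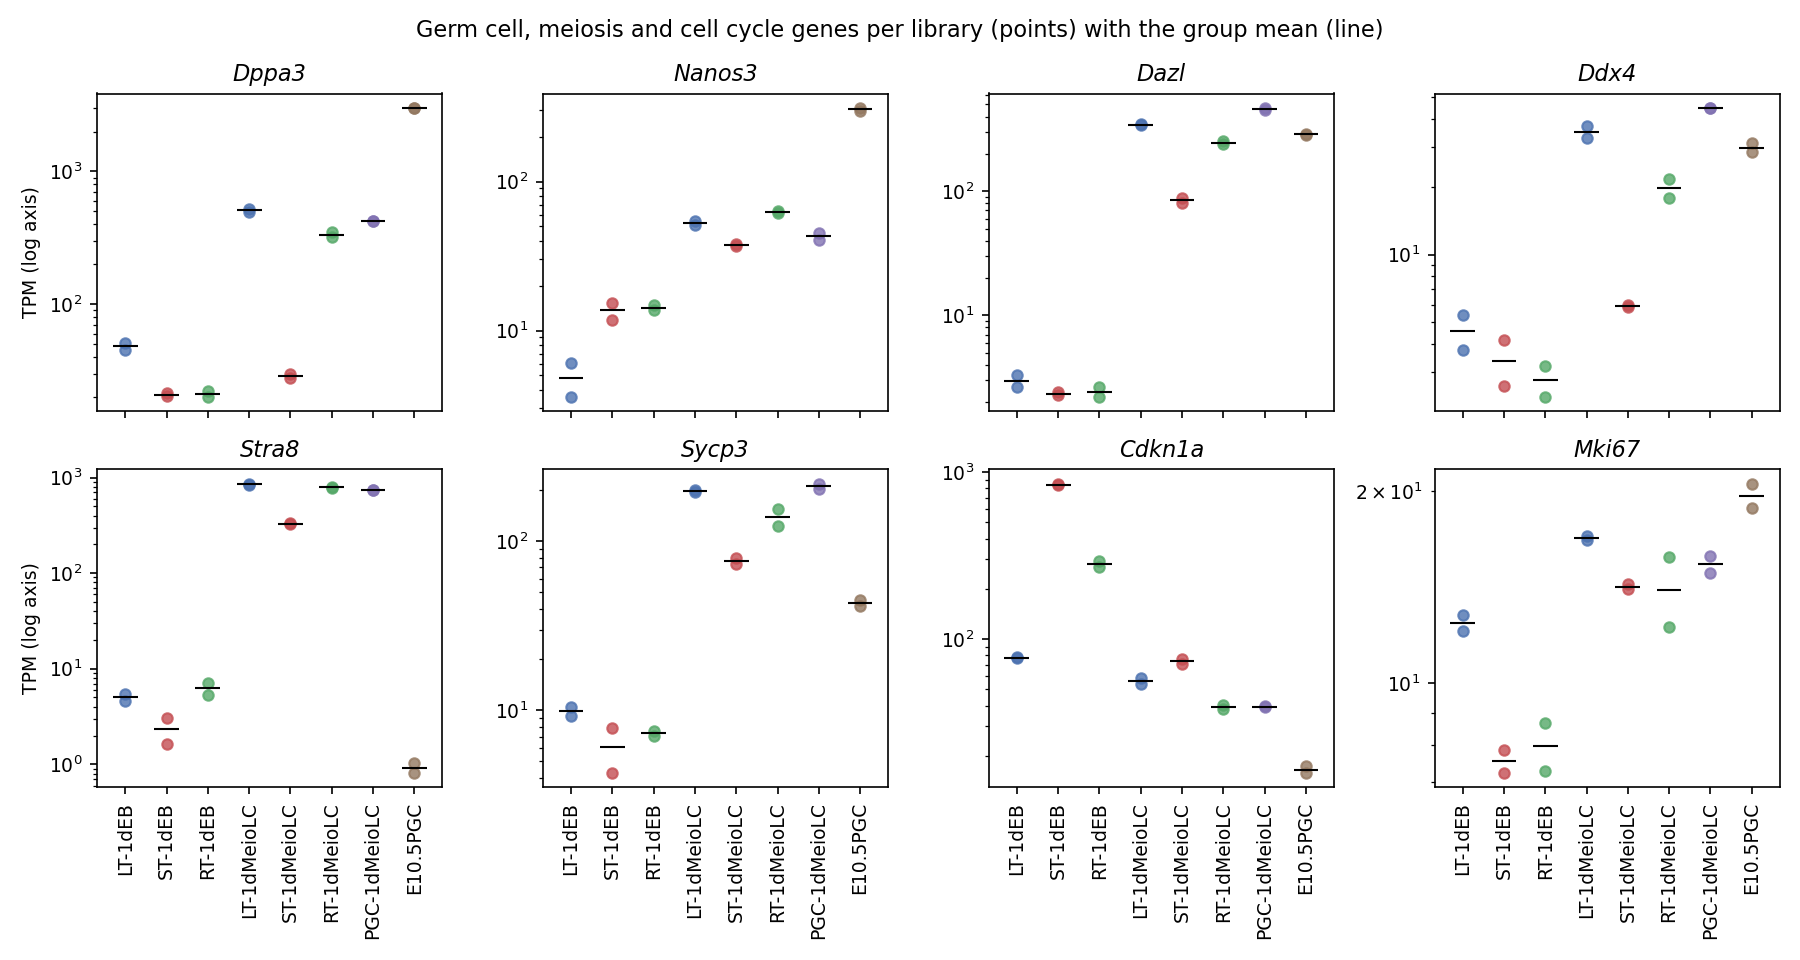
TPM on a log axis (vertical) of 8 genes in each library of the 8 groups (horizontal), with points for libraries and a line for the group mean. Dppa3, Dazl, Ddx4, Stra8 and Sycp3 were lower in ST 1dMeioLC than in LT, RT and PGC-derived 1dMeioLC, and Cdkn1a was highest in ST 1dEB at 841 TPM.

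Several pluripotency genes were higher in ST than in LT 1dMeioLC. Nanog, a core factor of pluripotency, rose from 28 ± 2.34 to 74.0 ± 3.46 TPM (SD, n = 2, log2 fold change 1.38, SE 0.10, limma adjusted p = 6.3e-06), and Fgf4, a growth factor of pluripotent cells, rose by 2.04 and Dppa2, a chromatin factor, by 1.43. 11 of 17 naive pluripotency genes were higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.0036; adjusted p = 0.11 with an estimated correlation). Formative and primed pluripotency genes were not called as a list (7 higher and 3 lower of 18, adjusted p = 0.1). Tdgf1, the Nodal co-receptor, was higher by 3.11. p53 targets were higher in 15 of 25 (camera adjusted p = 0.0015; 0.11), with Phlda3 at 2.08, while Cdkn1a was higher by only 0.38 (adjusted p = 0.0012). Retinoic acid response genes were higher in 10 of 14 (adjusted p = 0.025; 0.11), led by Hoxb1 (2.09) and Cdx1 (1.45), both homeobox genes of the posterior embryo. Proliferation genes were lower in 10 of 26 and higher in 2 (adjusted p = 0.026; 0.34), and early PGC genes in 10 and 6 of 20 (0.035; 0.3), with Rhox9 at -2.93 and Rhox5 at -2.91. Of the 15 anchors, 3 were higher (Tert, Cdkn1a and Prdm14), 7 lower (Kit, Dazl, Sycp3, Ddx4, Stra8, Dppa3 and Terc) and 5 not called (Prdm1, Tfap2c, Nanos3, T and Mki67). The call of Tert (0.60) was lost without LT replicate 1 (adjusted p = 0.11), ST replicate 1 (0.062) or ST replicate 2 (0.053), and Tfap2c was called lower without ST replicate 1 (0.0056).

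Cells of the gonadal co-culture were traced by their markers. Of 20 gonadal somatic markers 7 were higher and 6 lower in ST than in LT 1dMeioLC (limma camera adjusted p = 0.95), with Upk3b, of mesothelium, at 1.27, Bmp2 at -1.89, Dmrt1, of gonads and germ cells, at -1.79 and Fst, the activin antagonist, at -1.78. Stroma markers split into 6 higher and 6 lower of 16 (adjusted p = 0.83). Blood and endothelial markers were lower in 7 of 16 (adjusted p = 0.036; adjusted p = 0.11 with an estimated correlation), with the macrophage genes Tyrobp at -1.61 and Cd68 at -1.45. Interferon genes were not called as a list (5 higher and 2 lower of 21, adjusted p = 0.81). The interferon gene Ifna2 was nonetheless at 31.1 and 32.4 TPM in the ST libraries and listed at 0 in LT, and Ifna4 rose from 1.83 ± 0.701 to 84.7 ± 2.15 TPM (SD, n = 2), although near-identical copies of that family make the assignment uncertain. Pyy, a gut peptide, Tff2, a trefoil peptide, and Wfdc17, a macrophage protein, were listed at 0 in both ST libraries and stood at 34.4 and 33.6 TPM, 18.3 and 19.5 TPM, and 19.2 and 16.5 TPM in LT. In all 7692 genes were called, 3813 higher and 3879 lower, with 1027 and 1156 changed by at least 2-fold. With protein-coding scaling 4419 were higher and 3015 lower, and 16 of 19 late germ cell genes were still lower. Of the 8 list calls, those of late germ cell and meiosis genes held with an estimated correlation. Protein-coding scaling ended 3 of the 8.

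In RT 1dMeioLC most late germ cell genes were above ST. Dppa3 was at 334 ± 18.7 TPM (SD, n = 2), a log2 fold change over ST of 3.50 (SE 0.07, limma adjusted p = 1.1e-09), Ddx4 at 19.8 ± 2.75 TPM (1.59), Dazl at 247 ± 7.80 TPM (1.54) and Stra8 at 791 ± 12.2 TPM (1.26). Sycp3 was higher by 0.84, a call lost without RT replicate 1 (adjusted p = 0.062). 17 of 19 late germ cell genes were higher and 0 lower (camera adjusted p = 6.6e-12), with Slc25a31 at 2.10 and Mael at 1.81, and meiosis genes were higher in 16 and lower in 2 of 35 (adjusted p = 3.9e-05). Early PGC genes were higher in 8 and lower in 5 of 20 (camera adjusted p = 0.0088, and 0.19 with an estimated correlation). Tdgf1 (-2.43), Fgf4 (-1.07) and Nanog (-0.58) were lower. p53 targets were lower in 12 of 25 and higher in 1 (adjusted p = 5.8e-04; adjusted p = 0.084 with an estimated correlation), with Phlda3 at -1.37 and Cdkn1a at -0.88. Cholesterol biosynthesis genes were lower in 16 of 20 (adjusted p = 2.3e-07), with Srebf2, their master regulator, at -0.98 and Mvd, of the mevalonate pathway, at -0.88. Two-cell-like genes were higher in 7 of 12 (adjusted p = 6.4e-04), with Zscan4c at 2.07, of a family whose copies share reads. Of the 15 anchors 9 were higher (Kit, Dazl, Sycp3, Ddx4, Stra8, Dppa3, Nanos3, T and Terc). Another 4 were lower (Tert, Cdkn1a, Prdm1 and Prdm14) and 2 not called (Tfap2c and Mki67). T was near the floor, at a mean of 0.657 TPM in RT and 0.095 TPM in ST. The call of T was lost without ST replicate 2 (0.068) and that of Tert without RT replicate 2 (0.052). Calls numbered 7294, 2869 higher and 4425 lower (2286 and 5298 with protein-coding scaling, 3304 and 3493 with median-of-ratios scaling), and of the 12 list calls those of late germ cell, meiosis, two-cell-like and cholesterol genes held with an estimated correlation.

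RT 1dMeioLC still differed from LT in part of the germ cell genes. Dppa3 was lower by a log2 change of -0.61 (SE 0.07, limma adjusted p = 4.1e-04) and Dazl by -0.48 (adjusted p = 0.005), and Ddx4 was at -0.80 (adjusted p = 0.017), a call lost without LT replicate 1 (0.096), LT replicate 2 (0.056) or RT replicate 1 (0.098). Stra8 (-0.11, adjusted p = 0.75) and Sycp3 (-0.52, adjusted p = 0.091) were not called. 9 of 19 late germ cell genes were lower (camera adjusted p = 0.0022; adjusted p = 0.066 with an estimated correlation) and 11 of 35 meiosis genes (0.0011). Two-cell-like genes were higher in 8 of 12 (3.8e-09), with Zscan4c going from 1.66 ± 0.722 to 13.2 ± 1.61 TPM (SD, n = 2), and Obox6, an oocyte homeobox gene, at 3.14. Interferon genes were lower in 11 of 21 (2.2e-04), with the chemokine Cxcl10 at -1.46, cholesterol genes in 11 of 20 (4.6e-06), and gonadal somatic markers in 9 of 20 (0.0048), with Upk3b at -1.15 and Fst at -0.91. Of the 15 anchors T was higher, Dazl, Ddx4, Cdkn1a, Prdm1 and Dppa3 were lower and 9 were not called. T was near the floor, at a mean of 0.657 TPM in RT and listed at 0 in LT. The 4083 calls were 1361 higher and 2722 lower, and 1702 and 1824 with median-of-ratios scaling. This count fell by more than 1.5 times whichever of the 4 libraries was left out, and was lowest without LT replicate 2. Of the 13 list calls, 7 held with an estimated correlation, those of meiosis, retinoic acid, two-cell-like, interferon, cholesterol, gonadal somatic and histone genes.

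PGCs of the embryo gave the reference for the meiotic culture. Stra8 went from 0.920 ± 0.152 TPM (SD, n = 2) in E10.5PGC to 745 ± 2.34 TPM in PGC-1dMeioLC, a log2 fold change of 8.60 (SE 0.17, limma adjusted p = 2.0e-10), the retinoic acid oxidase Cyp26a1 rose by 5.99 and Sycp1, of the synaptonemal complex, by 4.05. Sycp3 rose by 2.26 and Dazl by 0.68. 28 of 35 meiosis genes were higher and 2 lower (camera adjusted p = 2.0e-05), and 11 of 14 retinoic acid response genes (9.1e-05). Dppa3 fell from 3010 ± 1.45 to 424 ± 1.49 TPM (-2.82) and Nanos3 from 306 ± 8.54 to 43.1 ± 3.28 TPM (-2.80), all 20 early PGC genes were lower (4.1e-15), as were all 26 proliferation genes (6.7e-15) and 12 of 17 naive pluripotency genes (1.8e-05). Markers of gonadal soma were higher in 17 of 20 (2.0e-07), with Nr2f2, of gonadal mesenchyme, at 4.47 and Wnt4, of female gonadal soma, at 3.64, and stroma markers in 14 of 16 (7.7e-08), with Col1a1 at 5.40. Imprinted genes were higher in 18 of 21 (1.2e-06), with H19 at 3.91. Gonadal cells left among the sorted cells would also lower PGC genes and raise genes of the soma. Whether the changes of early PGC, proliferation, pluripotency and imprinted genes came from such cells or from the germ cells was not tested. Of the 15 anchors 6 were higher (Dazl, Sycp3, Tert, Ddx4, Cdkn1a and Stra8). Another 8 were lower (Kit, Tfap2c, Mki67, Prdm1, Prdm14, Dppa3, Nanos3 and T), with T near the floor at 0.714 TPM in E10.5PGC. Terc was not called, though protein-coding scaling called it lower. The call of Ddx4 (0.57) was lost without any 1 of the 4 libraries (adjusted p of 0.059 and 0.12 without E10.5PGC replicates 1 and 2, 0.086 and 0.09 without PGC-1dMeioLC replicates 1 and 2). That of Kit was lost without either E10.5PGC replicate (0.069 and 0.11) or PGC-1dMeioLC replicate 1 (0.13), that of Mki67 without E10.5PGC replicate 2 (0.15) or either PGC-1dMeioLC replicate (0.12 and 0.055), and both with protein-coding scaling (0.36 and 0.2). That of Tert (0.46) was lost without E10.5PGC replicate 1 (0.14) or 2 (0.063) or PGC-1dMeioLC replicate 2 (0.25), and with quantile normalization Tert was at -0.01. In all 11768 genes were called, 7618 higher and 4150 lower (8524 and 3301 with protein-coding scaling, which moved the median of all genes from 0.13 to 0.28, and 5303 and 5684 with quantile normalization). Of the 13 list calls 9 held with an estimated correlation, those of meiosis, retinoic acid, early PGC, proliferation, naive pluripotency, gonadal somatic, stroma, imprinted and telomere maintenance genes (the last with 11 of 22 lower, 0.002).

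Stem-cell-derived 1dMeioLC were set against PGC-1dMeioLC, a comparison planned for LT and added for ST and RT after the data were seen. In LT the germ cell genes Ddx4, Stra8, Sycp3 and Nanos3 were not called, and Dazl was lower by a limma log2 change of -0.42, a call lost without LT replicate 2 (adjusted p = 0.055). Dppa3 (0.26) and Tfap2c (-0.48) were called with all libraries and lost without any 1 of the 4 (adjusted p between 0.059 and 0.13, and between 0.052 and 0.17). 7 of 19 late germ cell genes were lower (camera adjusted p = 6.5e-04, and 0.092 with an estimated correlation). Of 35 meiosis genes 6 were lower and 3 higher (camera adjusted p = 0.032, and 0.19 with an estimated correlation). In ST Dppa3 (-3.84), Ddx4 (-2.73), Dazl (-2.44) and Stra8 (-1.18) were all lower, with 19 of 19 late germ cell genes (7.6e-15) and 24 of 35 meiosis genes (1.1e-09). RT lay between, with 14 of 19 (4.2e-06), Dazl at -0.90, Ddx4 at -1.14 and Dppa3 at -0.34. Sycp3 was called lower in RT (-0.60), which was lost without PGC-1dMeioLC replicate 1 (0.094) or 2 (0.15) or RT replicate 2 (0.22). Interferon genes were higher in LT in 19 of 21 (3.8e-18), in ST in 18 (3.2e-10) and in RT in 16 (4.6e-11). Bst2, the antiviral tetherin, was at 40.2 ± 3.35 TPM (SD, n = 2) in LT against 2.41 ± 0.177 TPM, a log2 fold change of 3.59, and at 4.12 in ST and 4.75 in RT. Two-cell-like genes were higher in 10 of 12 in RT (7.4e-09). Of the 15 anchors 3 were higher (Cdkn1a, Dppa3 and Terc) and 2 lower (Dazl and Tfap2c) in LT, 3 higher (Tert, Cdkn1a and Prdm14) and 8 lower (Kit, Dazl, Sycp3, Ddx4, Tfap2c, Stra8, Prdm1 and Dppa3) in ST, and 3 higher (Nanos3, T and Terc) and 6 lower (Dazl, Sycp3, Ddx4, Tfap2c, Prdm1 and Dppa3) in RT. The calls of Prdm1 in ST and Nanos3 in RT were lost without any 1 of the 4 libraries (adjusted p between 0.086 and 0.17, and between 0.072 and 0.16), and that of Terc in RT without PGC-1dMeioLC replicate 1 (0.087) or 2 (0.086) or RT replicate 1 (0.18). Protein-coding scaling ended the calls of Dppa3 in LT, Prdm1 in ST and Nanos3 in RT and called Kit and Prdm14 lower in RT. T was near the floor, at a mean of 0.657 TPM in RT and listed at 0 in PGC-1dMeioLC. Calls numbered 4755 for LT (2946 higher and 1809 lower), 9176 for ST (5058 and 4118) and 6885 for RT (3150 and 3735), and with protein-coding scaling the splits were 1830 and 3031 for LT, 4460 and 4431 for ST and 2271 and 5290 for RT, where that scaling moved the median of all genes from -0.01 to -0.15. The LT count was between 2363, without LT replicate 2, and 3143, without LT replicate 1, when a library was left out. With an estimated correlation the LT list call of interferon held, 4 held for ST and 7 for RT, late germ cell, meiosis, two-cell-like and interferon genes among them in both.

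The reversal of ST changes in RT was counted gene by gene. Of the 5866 genes higher in ST than in LT at 1dEB, 4981 (84.9%) were lower in RT than in ST with raw TPM, and of the 2551 lower ones 302 (11.8%) were higher. This imbalance followed the scaling, since with protein-coding scaling the counts were 2537 of 4817 (52.7%) and 1836 of 4110 (44.7%). At 1dMeioLC, 2559 of 3813 (67.1%) and 1932 of 3879 (49.8%) went back with raw TPM, and 3152 of 4419 (71.3%) and 1483 of 3015 (49.2%) with protein-coding scaling. Both comparisons share the ST libraries, so part of the excess may come from the shared controls. With raw TPM, independent calls would share 2615 and 131 genes at 1dEB and 769 and 507 at 1dMeioLC. Simulations with no effect shared 0, but hardly any gene is called when nothing differs, so that count cannot gauge the shared controls. The covariance of raw log2 fold changes across genes was -0.343 at 1dEB and -0.347 at 1dMeioLC. Simulated values, which hold the shared noise alone, were -0.0451 and -0.0455. With raw TPM, calls of ST and RT against the shared LT libraries had the same direction for 1538 higher and 2061 lower genes at 1dEB (627 and 789 if independent, covariance 0.297 against 0.0451 simulated) and for 720 and 1269 at 1dMeioLC (237 and 481, covariance 0.166 against 0.0451). With protein-coding scaling the shared calls were 2848 higher and 1986 lower at 1dEB and 747 and 893 at 1dMeioLC.

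The ST effect was not the same gene by gene at both stages, which share no library. 1537 genes were higher and 763 lower in ST than in LT at both 1dEB and 1dMeioLC, where independent calls would share 1020 and 451, and the covariance of the log2 fold changes was 0.053. Cdkn1a and Phlda3 were higher at both stages and Dppa3, Rhox5, Rhox6 and Rhox9 lower at both. Col1a1 rose by 4.60 at 1dEB and was at 0.61 at 1dMeioLC (limma adjusted p = 7.1e-04), Mest had a log2 fold change of -3.89 at 1dEB and was at 0.24 (adjusted p = 0.0074). Dazl and Ddx4 were lower at 1dMeioLC and not called at 1dEB with raw TPM. Protein-coding scaling called Dazl lower at 1dEB (limma adjusted p = 0.0088). In LT 1dEB Dazl and Ddx4 stood at only 2.97 and 4.56 TPM, which limited how far both could fall at that stage. Tested as a difference between the stages, the ST effect was called for Dazl (-1.78, adjusted p = 2.8e-06), Ddx4 (-2.03, adjusted p = 2.1e-04) and Cdkn1a (-3.04, adjusted p = 1.2e-08).

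**Figure D3:**
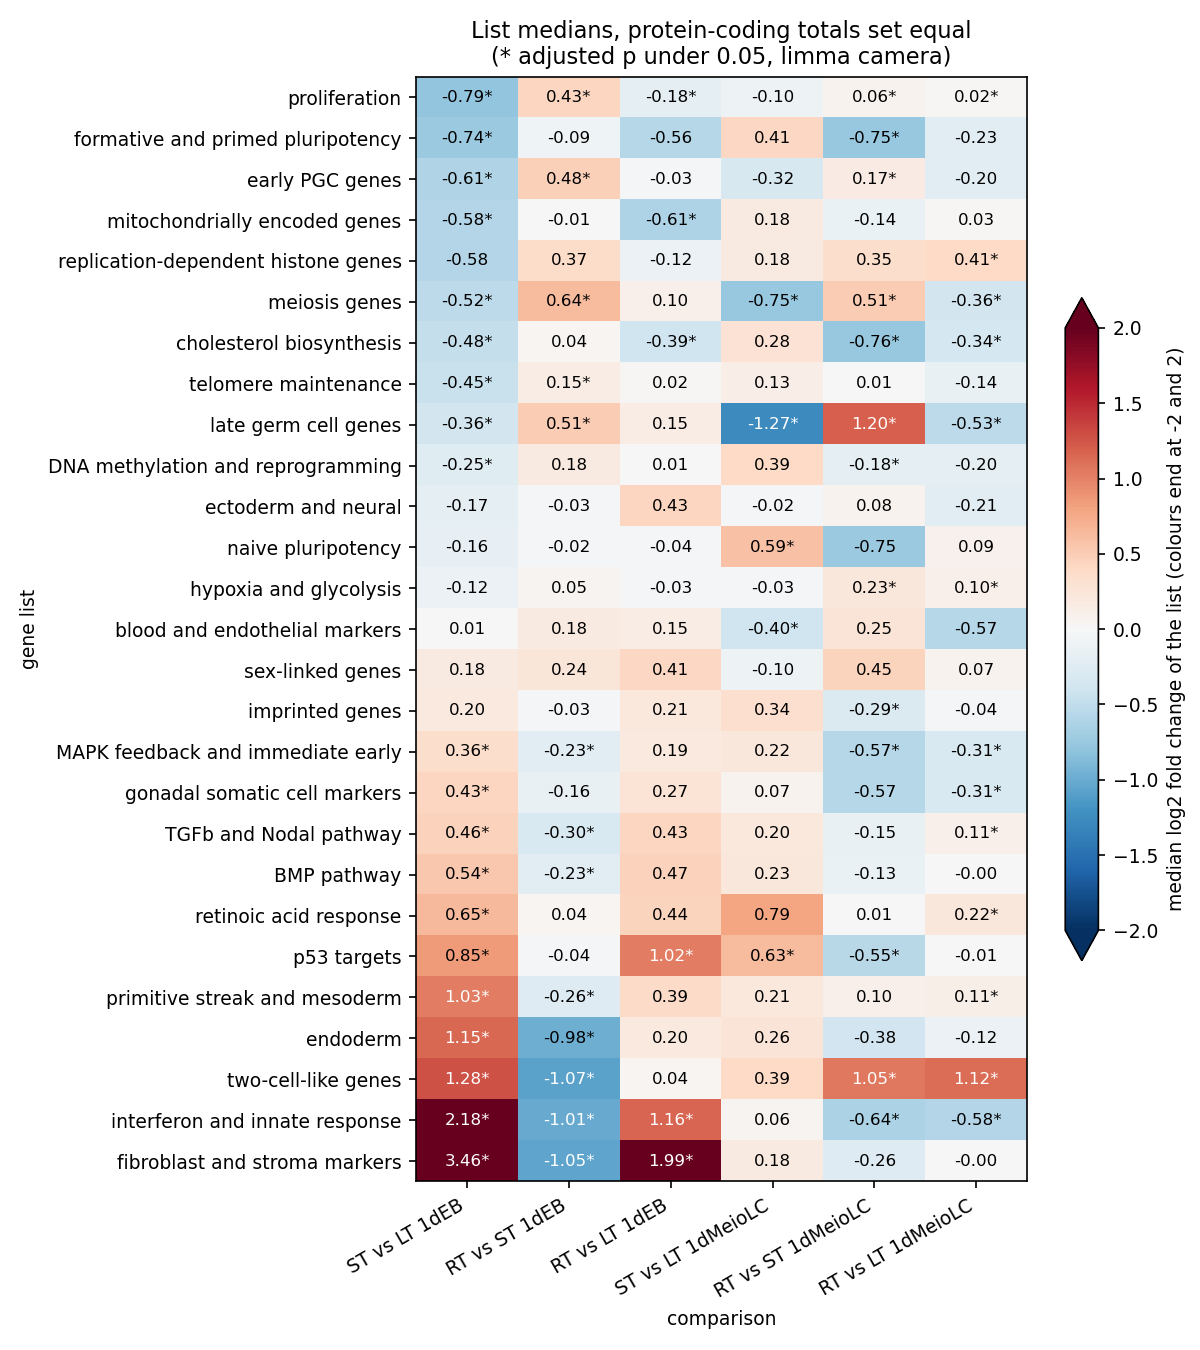
Median log2 fold change with protein-coding scaling of 27 gene lists in 6 comparisons (colour, with the value printed and a star where the camera adjusted p was under 0.05). Stroma markers had medians of 3.46 in ST and 1.99 in RT against LT at 1dEB, and late germ cell genes -1.27 in ST against LT and 1.20 in RT against ST at 1dMeioLC.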

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

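The tests of explanations in this part, and both comparisons of the stages, were chosen after the results were seen.

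The ST effect differed between the stages in a test of the difference itself (ST minus LT at 1dMeioLC against the same at 1dEB, limma interaction), which called 8471 genes, 2682 higher and 5789 lower. With protein-coding scaling the split was 4150 and 4129. Median log2 differences of the lists called by camera were -1.12 for late germ cell, 0.26 for naive and 0.55 for primed pluripotency, -1.09 for endoderm, -0.68 for MAPK feedback, -0.65 for BMP pathway, -0.64 for p53 targets, 0.45 for proliferation, 0.063 for telomere maintenance, 0.36 for DNA methylation, -2.05 for interferon, 0.51 for cholesterol, -3.22 for stroma, -1.12 for sex-linked and 0.52 for mitochondrially encoded genes. With a correlation estimated for each list 6 of these 15 calls held, those of late germ cell, primed pluripotency, proliferation, interferon, cholesterol and stroma genes, and protein-coding scaling ended the call of MAPK feedback genes (camera adjusted p = 0.071). Among the anchors the difference was -3.04 for Cdkn1a, -2.94 for Dppa3, -2.03 for Ddx4, -1.84 for Nanos3, -1.78 for Dazl, -0.99 for Prdm1, 0.88 for T and 0.94 for Tert, and the call of T was lost with a pseudocount of 0.1 (adjusted p = 0.061), while protein-coding scaling also called Mki67 higher. At the ends of the genes that the naming rule allows stood Snord64 (7.31), Mir6918 (5.14) and Ifna2 (5.02), and Npy (-7.20), Ctla2a (-7.57) and Pyy (-7.84). Snord64 and Mir6918 had large standard errors, 1.305 and 1.522 with protein-coding scaling. Where a group was listed at 0 the size depends on the pseudocount. Dazl and Ddx4 were low in LT 1dEB (2.97 and 4.56 TPM), which limited how far both could fall at that stage. T changed by -0.752 at 1dEB and 0.125 at 1dMeioLC, where it was listed at 0 in LT and at 0.095 TPM in ST.

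The change from ST to RT also differed between the stages (RT minus ST, limma interaction), with 9264 genes called, 7587 higher and 1677 lower, and 2735 and 4831 with protein-coding scaling. With raw TPM the median of all genes was 0.37, against -0.18 with protein-coding scaling, and the list medians were 0.96 for late germ cell, 1.11 for BMP pathway, 1.51 for two-cell-like, 0.86 for hypoxia, -0.09 for cholesterol and 1.40 for stroma genes, and none of these 6 camera calls held with an estimated correlation. With protein-coding scaling the medians were 0.47, 0.58, 1.88, 0.20, -0.78 and 0.79 in the same order, the call of hypoxia genes ended (camera adjusted p = 0.061), and those of two-cell-like (adjusted p = 0.012), cholesterol (0.012) and stroma genes (0.022) held with an estimated correlation. Among the anchors the difference with raw TPM and with protein-coding scaling was 3.49 and 2.76 for Dppa3 and 2.12 and 2.09 for T. T was under 1 TPM in ST and RT 1dMeioLC, and with raw TPM changed by -1.522 at 1dEB and 0.603 at 1dMeioLC. The differences were 1.79 and 1.21 for Ddx4, 1.5 and 0.83 for Dazl, -0.55 and -1.31 for Tfap2c, and -0.86 and -1.68 for Tert. Cdkn1a (0.69) and Nanos3 (0.66) were called with raw TPM, but with protein-coding scaling both changed sign and were not called (-0.07, adjusted p = 0.54, and -0.07, adjusted p = 0.86), and with median-of-ratios scaling neither was called (0.46 and 0.81), while protein-coding scaling also called Mki67 and Prdm14 lower. With raw TPM the call of Nanos3 was also lost without any 1 library except ST 1dEB replicate 1 (adjusted p from 0.079 to 0.16), and that of Tfap2c without any except ST 1dMeioLC replicate 2 (0.06 to 0.11). Among the genes that the naming rule allows, Pyy (8.48), Mir147 (6.29) and Mir125b-1 (6.18) were highest with raw TPM. Ifna4 (-6.42), Ifna2 (-4.91) and Mir7036b (-4.90) were lowest. The call of Mir7036b was lost without any 1 library except RT 1dEB replicate 2.

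Late germ cell genes fell in ST 1dMeioLC (18 of 19), and more gonadal somatic cells among the sorted cells, as the whole cause, would lower the genes of the stem-cell-derived cells and raise the somatic markers together. Meiosis genes (20 of 35) and early PGC genes (10 of 20) were lower as this needs, though 1 meiosis gene and 6 early PGC genes were higher. Yet 11 of 17 naive pluripotency genes, Nanog among them, were each called higher in ST and 3 lower, and the gonadal markers split into 7 higher and 6 lower. The share of TPM taken by rRNA and other non-coding transcripts is also argued against as the whole cause, since 16 of 19 were still lower with protein-coding scaling. What the Terc and telomere state of the line needs is there, since 17 of 19 were higher in RT than in ST 1dMeioLC. The fall and this return share the ST libraries, so a trait of those libraries alone would also put RT above ST. Against LT, 9 of 19 were still lower in RT. The Terc and telomere state cannot be separated from other differences between the lines. A fall within germ cells and a smaller share of germ cells among the sorted cells cannot be told apart here either. A larger somatic share may still be part of the pattern, since Wt1 (36.5 to 62.8 TPM) and Wnt4 (36.2 to 71.4 TPM), both of gonadal soma, were higher in ST although GFP-marked cells were sorted out.

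p53 targets (22 of 25) and stroma markers (15 of 16) rose in ST 1dEB. As the whole source, 1 kind of carried-over cell in different amounts would give all members 1 ratio of RT to ST excess over LT. This also needs the other cells to be alike between the lines. Yet 10 of the 19 p53 targets with an excess lay over 2 standard errors from their median ratio of 0.774. So did 11 of the 15 stroma markers from theirs of 0.370. The standard errors pool the spread between replicate libraries only, so variation of the carried-over cells is not in them. The share of TPM taken by rRNA and other non-coding transcripts is argued against for the p53 targets, since 19 of 25 were still higher with protein-coding scaling. What the Terc and telomere state of the line needs is there only in part for the stroma markers. Of these 13 of 16 were lower in RT than in ST with protein-coding scaling. All 16 were still above LT with that scaling, and 15 with raw TPM. The rise and this return share the ST libraries, so a trait of those libraries alone would also put RT below ST. For the p53 targets the count lower in RT was 7 of 25 with that scaling and 19 with raw TPM. Still above LT were 21 of 25 with that scaling and 13 with raw TPM, which leaves that state open for them. Carried-over cells of 1 kind as part of the source, of more than 1 kind, and a response of the cells themselves also stay open. These could act together.

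In RT against ST 1dEB, 9778 of 10905 calls were lower. With protein-coding scaling 47.8% were lower, but that scaling also moved the median of all genes from -0.38 to 0.05, so a near-even split largely follows from it. The share of TPM taken by rRNA and other non-coding transcripts and a lower level of many transcripts in RT cells therefore cannot be told apart here, and both stay open. No biological explanation was tested for the imbalance.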

How the results depend on the processing

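Protein-coding scaling was chosen after the data were seen, and the other alternatives before. Each count of called genes, and each count of list calls, that moved by more than 1.5 times is given here, and each named gene that changed direction. With a mean of at least 5 TPM fewer genes are tested, and the calls were 5154 in ST against LT, 7086 in RT against ST at 1dEB, 4316, 4248 and 2671 in ST against LT, RT against ST and RT against LT at 1dMeioLC, 6805 in PGC-1dMeioLC against E10.5PGC, 3071, 5183 and 4583 in LT, ST and RT 1dMeioLC against PGC-1dMeioLC, and 4790 and 5891 for the stage differences of ST minus LT and RT minus ST, with 3246 and 2679 genes going back in RT at 1dEB and 1dMeioLC. With an estimated correlation in place of the preset one the list calls went from 17 to 8 (ST against LT), 11 to 0 (RT against ST) and 11 to 5 (RT against LT) at 1dEB, from 8 to 2, 12 to 4 and 13 to 7 in the same order at 1dMeioLC, from 8 to 1, 10 to 4 and 11 to 7 for LT, ST and RT 1dMeioLC against PGC-1dMeioLC, and from 15 to 6 and 6 to 0 for the stage differences. RT against LT 1dEB had 7 list calls with median-of-ratios scaling, 5 with quantile normalization and 6 with protein-coding scaling, ST against LT 1dMeioLC had 5 with protein-coding scaling, and the stage difference of RT minus ST had 3 with a pseudocount of 0.1, 10 with quantile normalization and 10 with protein-coding scaling. Quantile normalization put Tert at -0.008 in PGC-1dMeioLC against E10.5PGC and Nanos3 at -0.084 in the stage difference of RT minus ST, where protein-coding scaling put Nanos3 at -0.072 and Cdkn1a at -0.07. For these list calls and genes the cause was not tested.

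Leaving out 1 library at a time leaves fewer samples and 1 group with 1 library, for which limma uses the spread pooled over the groups, so the lone library is assumed to vary like the others. The calls were then 6928 to 7323 in ST against LT, 9140 to 9870 in RT against ST and 7410 to 7733 in RT against LT at 1dEB, and 5222 to 6200, 5474 to 5867 and 1730 to 2675 in the same order at 1dMeioLC. They were 10078 to 10430 in PGC-1dMeioLC against E10.5PGC, 2363 to 3143, 7252 to 7636 and 4913 to 5309 in LT, ST and RT 1dMeioLC against PGC-1dMeioLC, and 6990 to 7744 and 8079 to 8633 for the stage differences. Genes called in ST against LT at both stages numbered 1645 to 2022 and those going back in RT 4535 to 5024 at 1dEB and 3298 to 3680 at 1dMeioLC. RT against LT 1dMeioLC and LT 1dMeioLC against PGC-1dMeioLC moved by more than 1.5 times, lowest without LT 1dMeioLC replicate 2. Of 216 values of named genes, direction and side of the threshold were the same for 213 with array weights, 208 with no filter, 207 with median-of-ratios scaling, 205 with a pseudocount of 0.1, 204 with protein-coding scaling, 204 with the compared stages fitted alone, 201 with quantile normalization and 171 of 172 with a mean of at least 5 TPM, and for 890 of 976 with a library left out. A replicate block over all groups left 215 of 216 and a block within each stage 204, and no count of called genes moved by more than 1.5 times with either block. Differences of replicate 1 minus replicate 2 correlated across genes between groups at -0.019 to 0.021 at 1dEB (3 pairs of groups) and -0.034 to 0.024 at 1dMeioLC (6 pairs), so the numbers give no sign of pairing. Planned and not run were the comparisons of epiblast-like and day-4 PGC-like cells and the count of genes called in ST against LT at all 4 stages, in place of which the count for both stages is given. With TPM alone the depth is unknown, so whether a value of 0 is absence or shallow sequencing was not tested.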

Other observations

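The genes in this part were chosen after their values were seen, and no explanation was tested for them.

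Mest, far lower in ST and RT than in LT at 1dEB, was high in every 1dMeioLC group, at 175 ± 0.803 TPM (SD, n = 2) in LT, 207 ± 0.315 TPM in ST, 182 ± 7.08 TPM in RT and 170 ± 1.93 TPM in PGC-1dMeioLC, against 24.9 ± 0.948 TPM in E10.5PGC. H19 stood at 515 ± 3.62, 693 ± 2.64, 495 ± 1.44 and 624 ± 31.6 TPM in the same order and at 40.7 ± 1.19 TPM in E10.5PGC, and Col1a1 had means of 119, 182, 118 and 187 TPM and of 3.48 TPM. Rhox5, an X-linked homeobox gene, was highest in E10.5PGC at 2548 ± 122 TPM, and in 1dMeioLC it was at 671 ± 8.08 TPM in LT, 89.1 ± 14.2 TPM in ST, 414 ± 14.2 TPM in RT and 597 ± 22.5 TPM from PGCs.

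Interferon-induced genes set stem-cell-derived 1dMeioLC apart from PGC-1dMeioLC. Ifitm3, a membrane protein that blocks virus entry and a marker of PGCs, was at 5407 ± 54.7 TPM (SD, n = 2) in LT, 4998 ± 14.6 TPM in ST and 4575 ± 50.1 TPM in RT against 891 ± 14.5 TPM in PGC-1dMeioLC, and Bst2 was at 58.6 ± 0.848 TPM in ST and 91.1 ± 3.79 TPM in RT 1dMeioLC and at 23.2 ± 3.21 TPM in E10.5PGC. Zscan4c was at 2.38 ± 0.640 TPM in ST 1dMeioLC and listed at 0 in both PGC-1dMeioLC libraries. Some sex-linked genes differed in ST against LT 1dMeioLC. Of 5 Y-linked genes measured, Eif2s3y (log2 fold change -1.44, limma adjusted p = 2.8e-05) and Zfy2 (-1.32, adjusted p = 2.4e-04) were lower, and Ddx3y, Uty and Zfy1 were not called. Xist, the RNA of X inactivation, went from 4.00 ± 0.284 to 8.62 ± 0.331 TPM (0.95, adjusted p = 5.5e-05). In ST against LT 1dEB the rise of Xist was larger (2.18), while Eif2s3y and Zfy2 stood at -0.04 and -0.20. The difference between the stages was called for Xist (-1.23, limma adjusted p = 5.7e-05).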
